A study of Mus musculus with 7 samples.

How the data were processed

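Total RNA from whole testis of mice aged 15 to 20 weeks was extracted with Trizol, and biotin-labelled cRNA was made from 2 ug of it and hybridised to Affymetrix expression arrays, per the labels' protocols. The series holds 7 arrays, 3 from Phf13 knockout mice and 4 from wild type mice. Groups were taken from the genotype given for each sample. The labels give each array a number of its own but do not state that the arrays came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

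The values are the authors' deposited table of log2 signals, 1 column per array and 45101 probe sets. Affymetrix Expression Console 1.4.1 is named in the submitters' processing notes. The method of summarisation, background correction and normalization is not given in the sources used here. That the values are on a log2 scale was read from their range, 1.59 to 13.92, and the column medians lay between 5.01 and 5.08. No normalization was added. Array data carry no read depth, and the number of arrays limits the precision; the median standard error of a log2 fold change was 0.0843. No detection calls were used here.

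Probe sets were named from a platform annotation table. Of the probe sets, 34958 had 1 gene symbol, 932 had several, and 9211 had no symbol there or were not listed. Array controls made up 64 probe sets, and under the rule below 3 tested genes (Actb, Gapdh and Pcx) were represented by control probe sets for their own transcripts. No symbol was changed through its gene identifier. Only probe sets with 1 symbol were tested, and each of 18194 genes was represented by the probe set with the highest mean over all 7 arrays. Chromosome and gene order came from a RefSeq gene table of the GRCm38.p6 assembly, which placed all but 161 genes. The array files name no assembly, so no coordinates are given.

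Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without trend or robust settings), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 fold changes are knockout minus wild type, and errors are standard errors of the fit or standard deviations (SD) between arrays, as named. The terms rose and fell are used for genes past that threshold. In all, 32 lists of cell type markers, pathways and complexes, holding 875 genes of which 772 were measured, were tested with limma's camera at a preset correlation of 0.01 and with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Counts of members past the threshold are given over all genes and adjusted over the list alone. Lists share members: 7 genes between the Leydig and steroid lists, 5 between the Sertoli and junction lists. Genes within 10 Mb of Phf13 were compared with all other genes by a two-sided Fisher's exact test with a 95% confidence interval. X-linked and Y-linked genes were tested as groups. Exact permutation tests ran over the 35 ways to divide the arrays into 3 and 4 and cannot give a p below 0.0286.

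The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. That rule took Phf13, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose knockout and wild type arrays did not overlap, up to 4 members of each list with the smallest unadjusted p, and the 4 genes of smallest unadjusted p near Phf13. Predicted genes and clone names were left out of the named genes and counted. Other list members named below, and Zbtb48, Klhl21, Camta1 and Samd11, were picked after their values were seen.

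The number that opens each array's title has no stated meaning. Arrays that share its first 4 digits form 3 groups, each with both genotypes, and were treated as a possible batch: knockout 1 with wild type 1, knockout 2 with wild type 2 and 3, and knockout 3 with wild type 4. Deviations from the genotype means correlated across genotypes at 0.103 to 0.319 within these title-number groups and at no more than 0.0227 outside them. Deviations sum to 0 within a genotype, so higher values within the groups pull those outside down. Wild type 2 and 3, the only pair of the same genotype in a group, correlated at −0.530, the lowest value among wild type pairs. No array pair shared over 8.09% of its values exactly, so no array was counted as a duplicate. Other alternatives were quantile normalization, median centring, leaving out the dimmest genes, the mean of all probe sets per gene, trend and robust settings, array weights, a replicate block, all probe sets, a plain test per gene and leaving out each array in turn. A floor for linear values was planned but did not apply to log2 values. Leaving out knockout 3 and wild type 4 together, and leaving out genes near Phf13, were added after the data were seen.

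The limma and camera steps were tested on simulated values for the 18194 genes of the knockout and wild type comparison. Of 200 changed genes, 73% of those moved by 0.5 and 99% of those moved by 1 on the log2 scale were recovered, with 10 false calls among 182. Camera called 2 of 2 lists of 25 genes shifted by 0.3 and 0 of the other lists. The simulated spread was independent between genes and held no title-number groups. It therefore cannot show how often camera makes false calls for lists of correlated genes. In the data the estimated correlation was 0.44 for the Sertoli list and 0.40 for the Leydig list.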

Results

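Gene expression was measured in whole testis of adult Phf13 knockout mice (n = 3 arrays) and wild type mice (n = 4 arrays) aged 15 to 20 weeks. Phf13 encodes a PHD finger protein that binds chromatin carrying histone H3 methylated at lysine 4. Each array gave log2 signals for 45101 probe sets, and array medians lay between 5.01 and 5.08. Pairwise Pearson correlations of the arrays across genes ran from 0.984 to 0.996. The first principal component held 51.5% of the variance, and the 3 knockout arrays (−25.1 to −17.1) lay apart from the 4 wild type arrays (7.23 to 27.4) on it. On the second (16.5%), knockout 2 (22.8) lay apart from knockout 1 (−9.66), knockout 3 (−10.5) and wild type (−5.54 to 6.23).

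Phf13 itself was lower in every knockout array. Its 1 probe set with a single gene symbol had a mean log2 signal of 5.86 ± 0.17 (SD, n = 3) in knockout and 8.64 ± 0.08 (SD, n = 4) in wild type testis. The signals were 6.04, 5.83 and 5.71 in the knockout arrays and 8.66, 8.64, 8.73 and 8.54 in the wild type arrays. The log2 fold change was −2.78 (SE 0.09, limma adjusted p = 8.76e-06), a level 6.88-fold lower. In an exact two-sided permutation test p was 0.0286, the smallest that 35 divisions of 7 arrays allow. The mean signal stood at percentile 42.5 of all tested genes in knockout and 81.4 in wild type. Whether the probe set lies inside the deleted part of the gene is not given in the sources used here. With the title-number groups as a block the log2 fold change was −2.78, with adjusted p = 0.000131.

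The question of the study's main contrast was which genes differ in testis without Phf13. Igfbp3, which binds insulin-like growth factors, rose by 1.43 on the log2 scale (SE 0.20), and the matrix proteoglycan gene Dcn rose by 1.23 (SE 0.19). Mme, which encodes the membrane peptidase neprilysin, rose by 1.53 (SE 0.15), 2.88-fold. The largest rise was that of the solute carrier gene Slc22a29, 2.31 (SE 0.33), from a wild type log2 signal of 3.68 ± 0.35 (SD, n = 4). The wild type signals of Slc22a29, Igfbp3 (4.87), Cldn10 (4.15) and Abi3bp (4.32) and the knockout signal of Tas1r1 (4.32) were below the array medians and were not shown to lie above background, so the sizes of these changes are uncertain. The falls were led by Phf13 and its neighbour Tas1r1, which encodes a taste receptor subunit and fell by 2.75 on the log2 scale (SE 0.10, adjusted p = 1.86e-05).

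The other largest rises were those of Lrg1 (1.39), Efemp1 (1.27), Cldn10 (1.21), the matricellular gene Sparcl1 (1.20), the fatty acid binding protein gene Fabp5 (1.20), the kallikrein gene Klk1 (1.19), Abi3bp (1.18) and Rgs2 (1.17), a regulator of G protein signalling. Their adjusted p-values and those of the rises above ran from 0.00703 for Mme to 0.0318 for Klk1. Among the falls, the receptor phosphatase gene Ptpro had a log2 fold change of −1.77 (SE 0.40), Mxra8 of −1.52 (SE 0.09), Zbtb8a of −1.33, the small heat shock protein gene Hspb7 of −1.19, the long non-coding RNA gene Pvt1 of −1.18 and Chgb, which encodes the secretory granule protein chromogranin B, of −1.17 (SE 0.10). Faap20, part of the Fanconi anaemia pathway, had a log2 fold change of −1.16, Tnfaip2 of −1.04, Klhl32 of −1.04 and C1qtnf12 of −1.02. Of these falling genes, Mxra8, Faap20 and C1qtnf12 lie within 10 Mb of Phf13 on chromosome 4, and Zbtb8a, Hspb7 and Klhl32 lie elsewhere on that chromosome.

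In all, 2934 of 18194 genes (16.1%) passed limma's adjusted p of 0.05, of which 1651 rose and 1283 fell. The excess of rises depends on the scaling and on dim genes: 1549 rose and 1680 fell with each array centred on its median, and 1529 rose and 1736 fell without the dimmest 50% of genes. The changes were small: the median absolute log2 fold change was 0.52 for genes that rose and 0.33 for genes that fell, and 48 genes rose and 13 fell by 2-fold or more. At an adjusted p of 0.1 there were 4745 genes, at an unadjusted p under 0.05 there were 6146 where 909.7 would be expected with no change, and 72 genes (57 higher, 15 lower) had a 2-fold difference with unadjusted p under 0.05. Knockout and wild type arrays did not overlap for 28.0% of genes, against 5.71% by chance. Among the called genes, 198 have predicted or clone names. With the title-number groups as a block 2317 genes passed (1402 rose, 915 fell). Of 117 named genes past the threshold, 95 stayed past it with this block and 22 did not: Klk1, Tspan8, Etv5, Foxo1, Dmrt1, Sohlh2, Pgam2, Crem, Tssk2, Tekt4, Spem1, Prm3, C1qc, Epb42, Aqp9, Fancd2, Polk, Cbx6, Tdrd3, Ifi27, Rdh11 and Cox8a. The count was 996 without knockout 1, 741 without wild type 1 and 1364 without wild type 2. It was 175 without knockout 3 and 4 without both knockout 3 and wild type 4. In each of these settings 100% of the 2934 genes kept the sign of their fold change. This was nearly fixed in advance: for 2894 of them the genotypes did not overlap, so leaving out arrays cannot turn the sign.

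Sertoli cell markers were higher as a group in knockout testis. Of 31 measured markers of these nurse cells of the seminiferous tubule, 23 rose, 0 fell and 8 did not pass, and adjusted over the list alone 25 rose. The median log2 fold change was 0.57 (camera adjusted p = 1.47e-15). The call was lost with an estimated correlation (adjusted p = 0.282 with an estimated correlation). Wt1, a transcription factor gene, rose by 0.78 (SE 0.09), the homeobox gene Rhox5 by 0.73 (SE 0.08), the cystatin gene Cst12 by 0.73 (SE 0.09) and the cathepsin gene Ctsl by 0.63 (SE 0.08). Sox9, which directs Sertoli cell fate, rose by 0.62 and Kitl, which encodes stem cell factor, by 0.87. Within the 3 title-number groups the list's median was 0.64, 0.46 and 0.57.

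Leydig cell markers, genes of the testosterone-producing interstitial cells, were higher as a group too. Of 22 measured, 13 rose, 0 fell and 9 did not pass, and adjusted over the list alone 18 rose. The median log2 fold change was 0.83 (camera adjusted p = 9.65e-11; adjusted p = 0.282 with an estimated correlation), and within the title-number groups it was 0.66, 0.67 and 0.78. Igf1 rose by 1.14 (SE 0.15), Pdgfra by 1.02 (SE 0.20), the fatty acid binding protein gene Fabp3 by 1.01 (SE 0.13) and Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, by 0.58 (SE 0.08). Of 15 measured genes of steroid hormone synthesis, 7 of which are on both lists, 3 rose, 0 fell and 12 did not pass, and 7 rose adjusted over the list alone. Their median was 0.42 (camera adjusted p = 0.000476; adjusted p = 0.282 with an estimated correlation). Cyp17a1 rose by 0.61 (SE 0.16) and Tspo, a mitochondrial cholesterol-binding protein gene, by 0.63 (SE 0.10), while Star had a log2 fold change of 0.93 (SE 0.29, adjusted p = 0.0590), which was 0.54 without knockout 3, and its adjusted p was 0.0363 with the title-number groups as a block. With 1 array left out, Cyp17a1 stayed past the threshold in 1 of 7 runs (log2 fold change 0.48 to 0.70). Of 20 genes of cholesterol synthesis and uptake, 5 rose, 0 fell and 15 did not pass, and 8 rose adjusted over the list alone (median 0.22, camera adjusted p = 0.00104; adjusted p = 0.463 with an estimated correlation). Insig1 rose by 0.94, Msmo1 by 0.93, Ebp by 0.83 and Hmgcs1, which makes HMG-CoA, by 0.79. Ebp and Nsdhl, 2 of the 5 that rose, are X-linked.

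Contractile, matrix and macrophage genes were higher too. Of 19 genes of peritubular myoid and vascular smooth muscle cells, 7 rose, 0 fell and 12 did not pass, and 9 rose adjusted over the list alone (median 0.32, camera adjusted p = 3.59e-05; adjusted p = 0.282 with an estimated correlation). The myosin light chain kinase gene Mylk rose by 0.92 (SE 0.12), the Hedgehog receptor gene Ptch1 by 0.77, Myl9 by 0.76 and smooth muscle actin Acta2 by 0.62. Of 26 genes of fibroblasts and extracellular matrix, 13 rose, 0 fell and 13 did not pass, with 13 adjusted over the list alone (median 0.24, camera adjusted p = 3.59e-05; adjusted p = 0.282 with an estimated correlation). Besides Igfbp3 and Dcn these included Bgn (0.60), Timp1 (0.58) and the basement membrane collagen gene Col4a1 (0.44). Of 25 genes of macrophages and monocytes, 7 rose, 0 fell and 18 did not pass, and 12 rose adjusted over the list alone (median 0.26, camera adjusted p = 0.000162; adjusted p = 0.408 with an estimated correlation). The protease gene Ctss rose by 1.11, the lysozyme genes Lyz1 by 1.06 and Lyz2 by 0.87, and the complement gene C1qc by 0.82. The macrophage median was 0.33, 0.14 and 0.57 within the title-number groups, and the myoid median was 0.13, 0.57 and 0.15.

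Genes of the blood-testis barrier and of cell junctions were also higher. Of 33 measured, 10 rose, 0 fell and 23 did not pass, and 12 rose adjusted over the list alone (median 0.19, camera adjusted p = 1.36e-05; adjusted p = 0.282 with an estimated correlation). The connexin gene Gja1 rose by 0.92 (SE 0.14), the Sertoli cell claudin gene Cldn11 by 0.73 (SE 0.11), the catenin gene Ctnna1 by 0.68 and the integrin gene Itgb1 by 0.59.

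**Figure D1:**
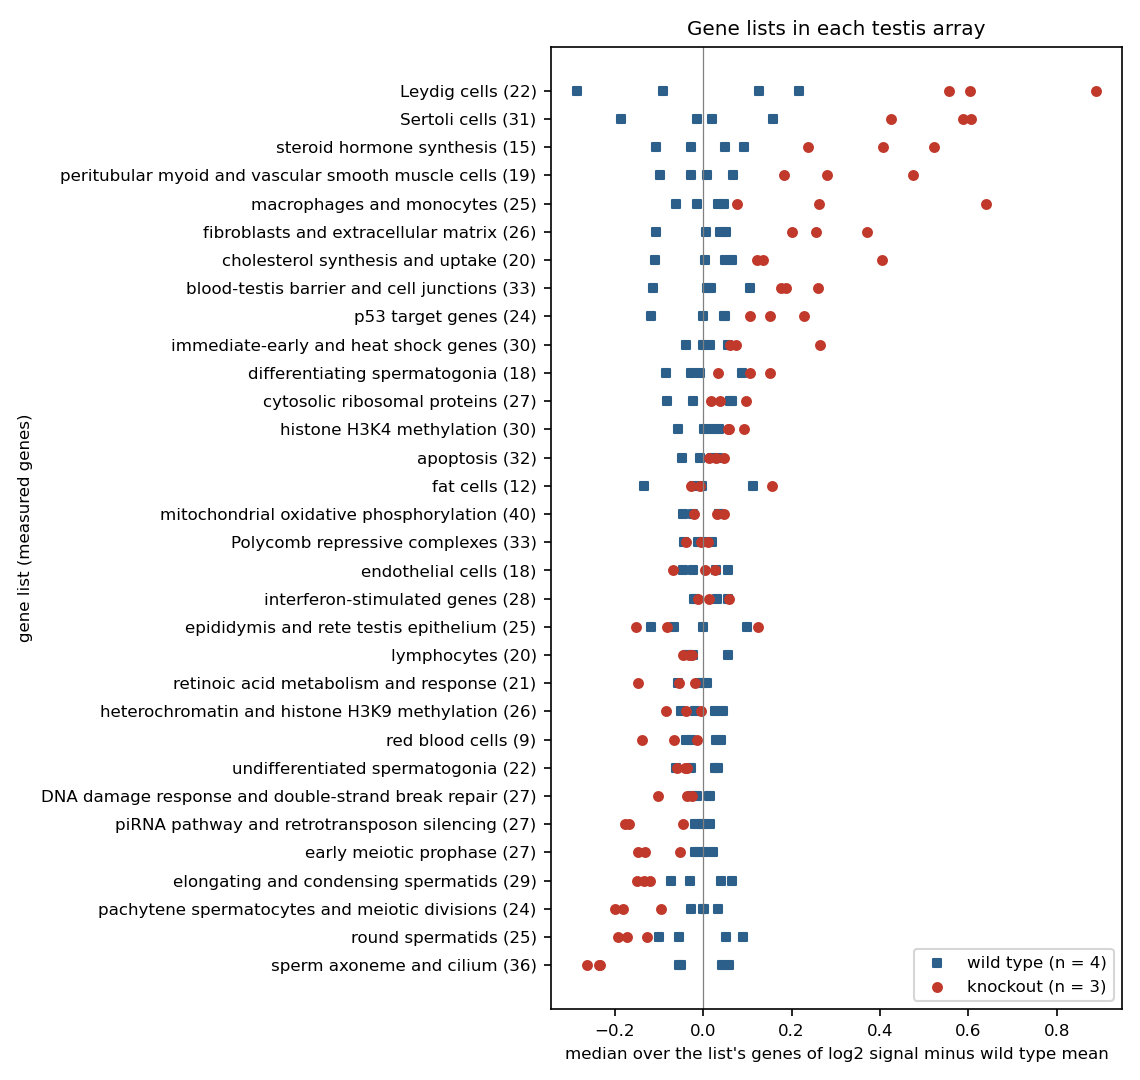
For each of the 32 gene lists (vertical axis, with the number of measured genes), each point is 1 array's median over the list's genes of log2 signal minus the wild type mean (horizontal axis, log2 units). Red circles are the 3 knockout arrays and blue squares the 4 wild type arrays; knockout arrays lie to the right for Sertoli and Leydig genes (median fold changes 0.57 and 0.83) and to the left for axoneme genes (−0.25).

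Genes of meiotic and later germ cells were slightly lower in knockout testis. For comparison, the median log2 fold change of all tested genes was −0.045. Of 36 genes of the sperm axoneme and cilium, the motile core of the sperm tail, 0 rose, 14 fell and 22 did not pass, and adjusted over the list alone 1 rose and 20 fell. Their median log2 fold change was −0.25 (camera adjusted p = 2.16e-06; adjusted p = 0.282 with an estimated correlation), and it was −0.30, −0.21 and −0.22 within the title-number groups. The dynein intermediate chain genes Dnaic2 (−0.52, SE 0.10) and Dnaic1 (−0.39, SE 0.07), the axonemal gene Ccdc40 (−0.42, SE 0.07) and the radial spoke gene Rsph9 (−0.31, SE 0.06) fell.

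Of 24 genes of pachytene spermatocytes and the meiotic divisions, 0 rose, 5 fell and 19 did not pass, and 8 fell adjusted over the list alone (median −0.17, camera adjusted p = 0.000681; adjusted p = 0.463 with an estimated correlation). The meiotic kinase gene Aurkc fell by 0.76 (SE 0.06), Plk1 by 0.44, the cyclin gene Ccna1 by 0.37 and Spata16 by 0.32. Of 25 genes of round spermatids, 0 rose, 3 fell and 22 did not pass, with 0 adjusted over the list alone (median −0.17, camera adjusted p = 0.000351; adjusted p = 0.504 with an estimated correlation). The 3 were Crem, a transcription factor gene of spermatids (−0.26), Pgam2 (−0.26) and the kinase gene Tssk2 (−0.22). Of 29 genes of elongating and condensing spermatids, 0 rose, 3 fell and 26 did not pass, with 0 adjusted over the list alone, and all 29 had a negative fold change (median −0.14, camera adjusted p = 0.000299; adjusted p = 0.512 with an estimated correlation). Spem1 (−0.32), Tekt4 (−0.30) and the protamine gene Prm3 (−0.24) fell. With the title-number groups as a block, none of Crem, Pgam2, Tssk2, Spem1, Tekt4 and Prm3 stayed past the threshold. Of 27 genes of the piRNA pathway and retrotransposon silencing, 0 rose, 6 fell and 21 did not pass, with 8 adjusted over the list alone (median −0.13, camera adjusted p = 0.00751; adjusted p = 0.463 with an estimated correlation). Among them Exd1 fell by 0.46, Dnmt3l by 0.44 and Henmt1, which methylates piRNAs, by 0.44.

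Earlier germ cells showed a mixed picture. Of 27 genes of early meiotic prophase, 0 rose, 2 fell and 25 did not pass, with 2 adjusted over the list alone (median −0.13, camera adjusted p = 0.0832, and 0.0262 without knockout 2; adjusted p = 0.520 with an estimated correlation). One of the 2 was Hsf2bp, a recombination gene (−0.27, SE 0.06), and the other has a clone name. Of 18 genes of differentiating spermatogonia, 2 rose, 0 fell and 16 did not pass, with 1 adjusted over the list alone (median 0.12, camera adjusted p = 0.0390; adjusted p = 0.504 with an estimated correlation). They were Sohlh2 (0.37) and Dmrt1 (0.35), and Dmrt1 is also on the Sertoli list. This list's median was 0.13, 0.16 and −0.06 within the title-number groups, and its adjusted p was 0.0638 without knockout 1, 0.0674 without wild type 1, 0.128 without knockout 2, 0.0750 without wild type 2, 0.0739 without the dimmest 33.3% of genes, 0.0669 without X-linked genes, 0.0720 with quantile normalization, 0.0521 with the replicate block and 0.227 with fry. Of 22 genes of undifferentiated spermatogonia, 3 rose, 0 fell and 19 did not pass, with 3 adjusted over the list alone: Tspan8 (0.97), Etv5 (0.49) and Foxo1 (0.28). With 1 array left out, Etv5 stayed past the threshold in 1 of 7 runs and Foxo1 in 0. This list's median was −0.08 and its mean 0.02 (camera adjusted p = 0.961; adjusted p = 0.965 with an estimated correlation).

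Markers of other cells that whole testis could hold were not past the test as groups. Most endothelial and lymphocyte genes were dim: 3 of 18 and 1 of 20 had a mean signal above the median of tested genes. Medians near 0 for these lists therefore say little about whether these cells changed. Of 18 endothelial genes, 0 rose, 1 fell and 17 did not pass, with 1 adjusted over the list alone (median −0.003, camera adjusted p = 0.899; adjusted p = 0.933 with an estimated correlation); the receptor phosphatase gene Ptprb fell by 0.40. Of 20 lymphocyte genes, 0 rose, 0 fell and 20 did not pass, with 0 adjusted over the list alone (limma; median −0.03, camera adjusted p = 0.905; adjusted p = 0.933 with an estimated correlation), and the T cell receptor gene Cd3d had a log2 fold change of −0.33 at an unadjusted p of 0.0193. Of 9 red blood cell genes, Epb42 (−0.24) fell, 0 rose and 8 did not pass, with 0 adjusted over the list alone (median −0.06, camera adjusted p = 0.679; adjusted p = 0.721 with an estimated correlation). Epb42 stayed past the threshold in 0 of 7 runs with 1 array left out. Of 25 genes of epididymis and rete testis, 1 rose, 1 fell and 23 did not pass, with 1 that rose adjusted over the list alone (median −0.02, mean 0.15, camera adjusted p = 0.864; adjusted p = 0.933 with an estimated correlation). The 2 were the lipocalin gene Lcn2, which neutrophils and stressed epithelia also express (1.04, SE 0.19), and the water channel gene Aqp9 (−0.28). Of 12 fat cell genes, 0 rose, 1 fell and 11 did not pass, with 0 adjusted over the list alone (median 0.04, camera adjusted p = 0.679; adjusted p = 0.864 with an estimated correlation); the hormone-sensitive lipase gene Lipe fell by 0.32.

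Stress and cell death genes were higher in part. Of 32 apoptosis genes, 8 rose, 1 fell and 23 did not pass, with 9 and 1 adjusted over the list alone (median 0.04, camera adjusted p = 0.0199; adjusted p = 0.282 with an estimated correlation). Birc3 (0.73) and Bcl2l2 (0.55), which oppose cell death, rose, as did cytochrome c Cycs (0.70) and the caspase gene Casp6 (0.55). Of 24 p53 target genes, 3 rose, 1 fell and 20 did not pass, with 4 and 1 adjusted over the list alone (median 0.18, camera adjusted p = 0.00290; adjusted p = 0.282 with an estimated correlation). Ccng1 rose by 0.82, Sesn1 by 0.47 and Ei24 by 0.43, and the DNA polymerase gene Polk fell by 0.36. Of 30 immediate-early and heat shock genes, 7 rose, 1 fell and 22 did not pass, with 7 and 1 adjusted over the list alone (median 0.15, camera adjusted p = 0.0121; adjusted p = 0.282 with an estimated correlation). The adjusted p was 0.215 without the dimmest 33.3% of genes and 0.264 without the dimmest 50%. Klf6 and Hspa1b rose by 0.59 each, Hspb1 by 0.56 and Jun by 0.50. Of 27 genes of the DNA damage response and double-strand break repair, 0 rose, 1 fell and 26 did not pass, with 0 adjusted over the list alone (median −0.09, camera adjusted p = 0.286; adjusted p = 0.721 with an estimated correlation). The one that fell was Fancd2 (−0.28). Of 28 interferon-stimulated genes, 3 rose, 1 fell and 24 did not pass, with 4 and 2 adjusted over the list alone (median −0.01, mean 0.05, camera adjusted p = 0.422; adjusted p = 0.685 with an estimated correlation). Ifi35 rose by 0.72, Xaf1 by 0.63 and Ifi27 by 0.40, and Dhx58 fell by 0.34.

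Phf13 is a chromatin reader, so chromatin genes were tested. Of 30 genes of histone H3K4 methylation, 3 rose, 0 fell and 27 did not pass, with 6 and 1 adjusted over the list alone (median 0.06, camera adjusted p = 0.0271; adjusted p = 0.408 with an estimated correlation). The methyltransferase gene Kmt2c rose by 0.73 (SE 0.15), Wdr82 by 0.55 and the demethylase gene Phf8, which is X-linked, by 0.48. The list's adjusted p was 0.0913 without X-linked genes, 0.0985 without the dimmest 33.3% of genes and 0.192 without the dimmest 50%. Of 26 genes of heterochromatin and histone H3K9 methylation, 3 rose, 1 fell and 22 did not pass, with 5 and 1 adjusted over the list alone (median −0.06, mean 0.04, camera adjusted p = 0.810; adjusted p = 0.933 with an estimated correlation). The X-linked chromatin remodeller gene Atrx rose by 1.04 (SE 0.13), the linker histone gene H1f2 by 0.82 and the methyltransferase gene Ehmt1 by 0.48, and Dnmt3l fell. Of 33 Polycomb genes, 5 rose, 2 fell and 26 did not pass, with 6 and 2 adjusted over the list alone (median 0.002, camera adjusted p = 0.241; adjusted p = 0.685 with an estimated correlation). The X-linked gene Rbbp7 rose by 0.80, Jarid2 by 0.38, Pcgf3 by 0.36 and Cbx6 by 0.36.

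Metabolic and ribosomal lists had medians near 0. Of 40 genes of oxidative phosphorylation, 7 rose, 0 fell and 33 did not pass, with 7 adjusted over the list alone (median 0.01, camera adjusted p = 0.0645; adjusted p = 0.685 with an estimated correlation), Ndufa4 by 0.64 and the X-linked Ndufa1 by 0.42. The adjusted p was 0.00198 with quantile normalization, 0.0306 without knockout 1, 0.0360 without wild type 3, 0.0363 without wild type 4, 0.0442 without knockout 3 and wild type 4, 0.0389 with the replicate block and 0.0448 with the title-number block. Of 27 cytosolic ribosomal protein genes, 1 rose, 0 fell and 26 did not pass, with 1 adjusted over the list alone (median 0.07, camera adjusted p = 0.0314; adjusted p = 0.685 with an estimated correlation). It was the X-linked gene Rps4x (0.98, SE 0.18), of which a dimmer second probe set had a log2 fold change of −0.22. The ribosomal list's adjusted p was 0.123 without wild type 1, 0.122 without knockout 2, 0.0513 without wild type 2, 0.0692 without the dimmest 33.3% of genes, 0.0668 with each array centred on its median, 0.0670 with the mean of all probe sets per gene and 0.270 with fry. Of 21 genes of retinoic acid metabolism and response, 2 rose, 3 fell and 16 did not pass, with 3 and 6 adjusted over the list alone (median −0.06, mean 0.009, camera adjusted p = 0.961; adjusted p = 0.965 with an estimated correlation). The retinoic acid synthesis gene Aldh1a1 rose by 0.85 (SE 0.09) and the degradation gene Cyp26b1 by 0.56, and Stra6 (−0.39) and Rdh11 (−0.24) fell.

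Over the 32 lists, 14 were higher and 5 lower by camera at the preset correlation, and 18 of these 19 had a median of that sign in each title-number group. With an estimated correlation 0 lists passed, 4 had an unadjusted p under 0.05, and fry called 13. The calls that fry did not make were those of the differentiating spermatogonia, round spermatid, macrophage, cholesterol, H3K4 methylation and ribosomal lists. In an exact permutation test of the array means, chosen after the results were seen, knockout and wild type arrays did not overlap for 17 of the 19 lists, and the smallest p after adjustment over the lists was 0.0610.

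X-linked genes were higher in knockout testis. Of 617 tested, 194 (31.4%) rose and 0 fell. On the autosomes, 6.59% to 11.3% of the genes of each chromosome rose and 5.23% to 8.79% fell. For the X-linked group, camera gave an adjusted p = 8.61e-20 over both sex chromosomes. The call held with an estimated correlation (adjusted p = 0.0307 with an estimated correlation). The median log2 fold change was 0.18, and 0.20, 0.19 and 0.15 within the title-number groups. Among the X-linked genes named above, Atrx rose by 1.04, Rps4x by 0.98, Ebp by 0.83, Rbbp7 by 0.80 and Rhox5 by 0.73. Of 9 Y-linked genes 0 rose and 0 fell by limma, with a median of 0.13 and a camera p of 0.0730 (adjusted p = 0.121 with an estimated correlation).

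**Figure D2:**
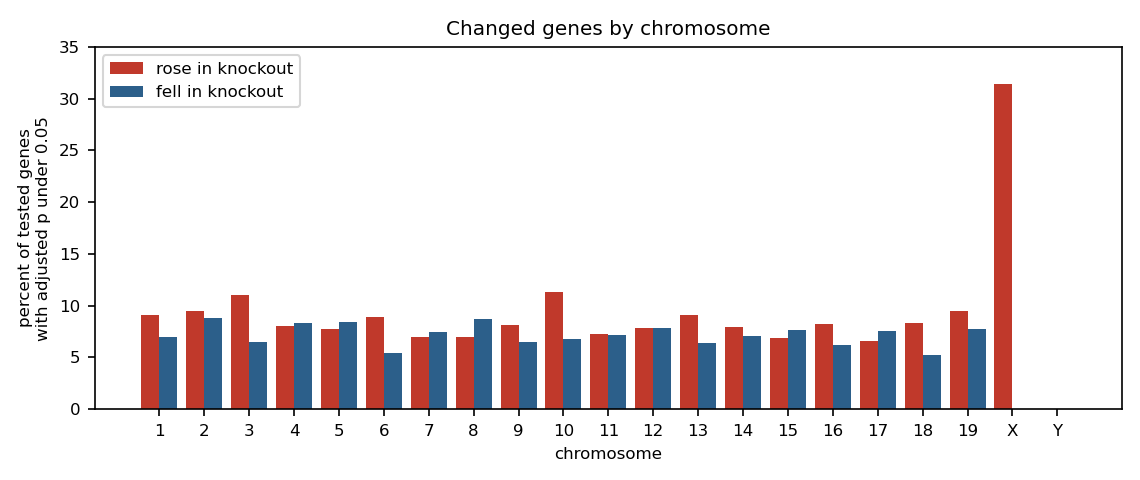
Bars give, for each chromosome (horizontal axis), the percent of tested genes past an adjusted p of 0.05 (vertical axis) that rose (red) or fell (blue) in knockout testis (n = 3) against wild type (n = 4). Chromosome X stands apart, with 31.4% of its genes higher and 0 lower.

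Genes around Phf13 on chromosome 4 included several of the clearest falls. Tas1r1, 3 tested genes away from Phf13, was at 4.32 ± 0.21 (SD, n = 3) in knockout and 7.07 ± 0.10 (SD, n = 4) in wild type. Mxra8 was 2.88-fold lower (log2 fold change −1.52, SE 0.09, limma adjusted p = 0.000695), Faap20 2.23-fold lower (adjusted p = 0.00155) and Ttc34 1.80-fold lower (−0.85, SE 0.07, adjusted p = 0.00278). The next 2 tested genes, Klhl21 (−0.55) and Zbtb48 (−0.77), fell, while Camta1 (0.72), on the other side, and the more distant Samd11 (0.95) rose. Of 162 tested genes within 10 Mb, 9 rose and 24 fell, 20.4% against 16.1% of all others. The odds ratio was 1.33 (95% interval 0.880 to 1.97), and Fisher's exact test gave p = 0.162. In this fit, which has no block, the share of changed genes was not distinguishable from that elsewhere. With the title-number groups as a block p was 0.00603, and it was 7.39e-05 without knockout 1, 9.75e-06 without wild type 1, 0.00375 without wild type 2 and 3.66e-06 without knockout 3.

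**Figure D3:**
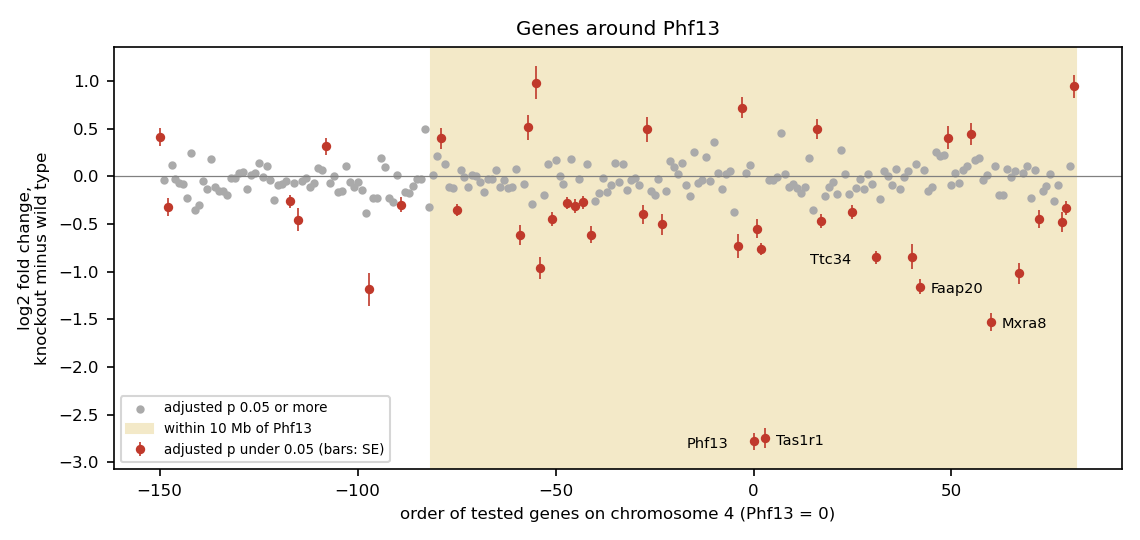
Each point is a tested gene in its order along chromosome 4 with Phf13 at 0 (horizontal axis), with its log2 fold change, knockout (n = 3) minus wild type (n = 4), on the vertical axis. Red points have an adjusted p under 0.05 and bars of 1 standard error, and the shaded stretch is within 10 Mb of Phf13; Phf13 (−2.78) and Tas1r1 (−2.75) lie lowest.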

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

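In this part, the tests chosen only after the result was seen were the comparison of cell type shifts, the test of RNA quality, the count of splits for X-linked genes, the splits that follow the title-number groups, the fit with the Sertoli and Leydig score as a term for genotype, and near Phf13 the count among the 20 genes of smallest p by Fisher's test, the test on adjacent genes and the count of genes without a second probe set; the other tests were planned before their results were seen.

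Among the 4 wild type arrays, 1 array was set apart from the other 3 for 8 of 181 values checked. That is no more than the about 1 in 20 that chance gives. The rule compared the gap with the range of the 4 values (limit 0.829), so some of these gaps are small. Wild type 3 had a log2 signal of 9.53 for Klk1 (mean of the others 8.89) and a lymphocyte list median of 0.055 (others −0.03). Wild type 4 had 12.11 for Pgam2 (others 12.21) and 8.52 for Dnaic1 (others 8.70). Wild type 2 had 5.79 for Cd3d (others 5.55), 4.89 for Hbb-b2 (others 5.28) and 6.11 for Hspa1b (others 6.36). Wild type 1 had 5.80 for Cd3e (others 5.76). Outside the named genes, 334 of 10092 probe sets without a single gene symbol passed the threshold, 222 higher and 112 lower. Probe sets 1451635_at (2.71) and 1431685_at (1.99) had the highest log2 fold changes and 1439280_at (−1.12) and 1453347_at (−1.11) the lowest. The wild type signal of 1451635_at (3.98) and the knockout signal of 1439280_at (4.81) were below the array medians. The sizes of these changes are therefore uncertain.

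The first pattern is the grouping of strong changes near Phf13. Of the 20 genes of smallest p, 5 besides Phf13 lie within 10 Mb (Tas1r1, Mxra8, Faap20, Ttc34 and Zbtb48), where 0.169 would be expected (Fisher's exact p = 5.53e-07). Of 35 splits of the arrays 1, the real one, gave 5 such genes, against at most 1 in the others. That share of 0.0286 is under 0.05 but is the smallest that 35 splits allow. It was not adjusted over the patterns, so chance is not excluded. Other probe sets above the median signal cover 12 of 33 changed genes near Phf13, and of the 5 only Faap20. Of these probe sets 68% moved the same way with unadjusted p under 0.05 (61.3% elsewhere). This argues against sequence differences under single probe sets for those 12 genes as a set. It does not for Vamp3 (−0.73, others −0.22, 0.24 and −0.003), Morn1 (−0.84, other 0.07) and Agtrap (−0.31, other −0.08). Since 4 of the 5 genes have no second probe set above the median signal, for Tas1r1, Mxra8, Ttc34 and Zbtb48 a strain variant under the probe set and a true change in transcript cannot be told apart. An effect confined to adjacent genes stays open for Tas1r1 and Zbtb48 but would not cover the other 3, which lie beyond 1 Mb. Beyond 1 Mb 0.129 genes would be expected among the 20 (Fisher's exact p = 0.00027). Of these 3, Faap20 alone has other probe sets above the median signal, both lower too. A neighbouring stretch from the strain of the targeted stem cells may carry regulatory variants, and this stays open with an effect of Phf13 itself, since the labels give no strain.

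The second pattern is the rise of Sertoli, Leydig, myoid, matrix and macrophage lists beside lower spermatid and axoneme lists. Chance could not be excluded for the number of lists: 3 of 35 splits gave as many as the real 19, namely wild type 1, 2 and 3 (19) and wild type 1, 2 and 4 (20) against the rest, which both keep all 3 knockout arrays together and so carry much of the real contrast, while splits that part the knockout arrays gave at most 17. RNA quality stays open: 3' minus 5' signals of 4 control transcripts differed by 0.0194 between genotypes on average (exact p = 0.514), but that of pyruvate carboxylase was 0.19 higher and that of the transferrin receptor 0.12 lower in knockout, and that of 18S rRNA, which was not in this mean, was −0.78 in both knockout 3 and wild type 4, which share a title-number group, against −0.11 to 0.22 in the other arrays. A lower share of germ cells that raises all other cells alike may account for the pattern: Sertoli genes shifted by 0.58, myoid genes by 0.48 and macrophage genes by 0.46, and Leydig genes by 0.77 (exact p for the differences from Sertoli 0.257, 0.229 and 0.143). Against it, Sertoli and Leydig genes shifted by 0.76 more than endothelial and lymphocyte genes (exact p = 0.0286, the smallest possible), but the latter were 4 genes above the median signal, too few to decide (a limit set after the value was seen), so a lower germ cell share and regulation within these cells cannot be told apart.

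The third pattern is the rise of X-linked genes. Of the 35 splits 1, the real one, gave a camera p for X-linked genes as small as 4.30e-20. The next gave 1.57e-18 (wild type 1, 2 and 3 against the rest, which keeps the knockout arrays together). The share of 0.0286 is under 0.05 but is the smallest that 35 splits allow. It was not adjusted over the patterns, so chance is not excluded. A varying share of Sertoli and Leydig RNA may account for part of it: among arrays of one genotype, X-linked genes went with a score of 50 autosomal Sertoli and Leydig genes (median slope 0.272, against 0.021 for other genes; camera p = 1.64e-06, and 0.00627 with an estimated correlation). With the score as a term the X-linked median was 0.06 against −0.05 for other genes (camera p = 0.000285, and p = 0.0164 with an estimated correlation), but score and genotype correlate at 0.923 and the median standard error rose from 0.0843 to 0.204, so that even Phf13 (−2.68, SE 0.24, limma adjusted p = 0.0876) was not past the threshold and single genes say nothing here. Incomplete silencing of the X chromosome in germ cells of the knockout stays open for that remainder, as does a share of other somatic cells, and neither was tested.

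For the number of genes past the threshold, of the 35 splits 1, the real one, gave 2934 genes and the highest other gave 3. Here too the share of 0.0286 is under 0.05 but is the smallest that 35 splits allow, and chance is not excluded. The 35 splits leave aside that arrays of different genotype in a title-number group tended to deviate in the same way. Only 12 splits take 1 array from each of these groups, too few for a share under 0.05. Among these 12 the real split gave 2934 genes against at most 2, 5 genes near Phf13 against 0, and a camera p for X-linked genes of 4.30e-20 against 6.00e-18, while for lists the highest other was 20 against 19.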

How the results depend on the processing

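Leaving out knockout 3 with wild type 4, and leaving out genes near Phf13, were chosen after the data were seen; all other alternatives were planned. Phf13 stayed lower in every setting (log2 fold change −2.87 to −2.71 with 1 array left out), and the X-linked median stayed above 0 (0.173 to 0.203 with 1 array left out, 0.35 and 0.40 without the dimmest 33.3% and 50% of genes). The number of genes past the threshold was 175 (knockout 3 left out) to 2574 with 1 array left out (96 to 1524 higher, 79 to 1210 lower). It was 4 without knockout 3 and wild type 4 (1 higher, 3 lower) and 17 with a plain test per gene (1 higher, 16 lower). Fewer arrays enter the former, and the latter borrows no spread across genes. The number of arrays alone does not set the count, which was 175 without knockout 3 but 2500 without knockout 2. Likewise it was 741 without wild type 1 but 2574 without wild type 3. Knockout 2 lay apart from knockout 1 and 3 on the second principal component. Whether this or something else acts on the count was not tested. With all probe sets 2527 were higher. Of 117 named genes past the threshold, 30 stayed past it without knockout 3 and 3 without knockout 3 and wild type 4. All kept the same sign, which is fixed in advance for genes whose knockout and wild type arrays do not overlap. No detection calls were used; leaving out the dimmest 33.3% gave 3451 genes and the dimmest 50% gave 3265, and the cause was not tested.

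The replicate numbers in the titles were not shown to pair the arrays. Deviations of same-numbered arrays correlated at 0.18 and 0.10 for numbers 1 and 2, which also share a title-number group. For number 3, where the arrays do not share one, the value was −0.14. With the replicate block 2294 genes passed, of which 660 were lower.

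The changed genes near Phf13 numbered 10 to 29 with 1 array left out and 2 without knockout 3 and wild type 4 (Fisher's exact p = 0.000235). Without knockout 2, wild type 3 or wild type 4 their share was not past the threshold (Fisher's exact p = 0.0705 to 0.257). With the replicate block, quantile normalization, array weights, centring, trend and robust settings or without the dimmest 50%, p ran from 0.0557 to 0.739. By Fisher's exact test their share was past the threshold with the title-number block (33 genes), with the mean of all probe sets (38, p = 0.00393), and turned below that of other genes without the dimmest 33.3% (33, p = 1). The cause was not tested. The number of lists was 17 to 20 with 1 array left out, 20 without knockout 3 and wild type 4, 15 without the dimmest 33.3% of genes, 17 without the dimmest 50%, 13 with fry and 0 with an estimated correlation, which allows for correlation between the genes of a list.

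None of the lists past the threshold turned direction. Lists not past it had adjusted p-values, with the direction turned, of 0.940 (quantile), 0.773 (dimmest 33.3% out), 0.720 (fry) and 0.970 (without knockout 3 and wild type 4) for endothelial cells; 0.961 (centring), 0.798 and 0.388 (dimmest 33.3% and 50% out), 0.991 (title-number block) and 0.780 (without knockout 3 and wild type 4) for retinoic acid; 0.304 (dimmest 33.3% out), 0.993 (trend), 0.946 (array weights) and 0.904 (without knockout 3 and wild type 4) for undifferentiated spermatogonia; and 0.917 (replicate block) for epididymis. With 1 array left out, the adjusted p-values of these and other lists not past it, in whichever direction, ran from 0.521 to 0.969 for endothelial cells, 0.821 to 0.993 for retinoic acid, 0.795 to 0.989 for undifferentiated spermatogonia, 0.263 to 0.987 for epididymis, 0.788 to 0.928 for lymphocytes, 0.411 to 0.994 for fat cells and 0.566 to 0.994 for heterochromatin. Slc2a4, not past the threshold, had a log2 fold change of 0.018 with the mean of all probe sets, against −0.15 with 1 probe set. The cause was not tested.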

Other observations

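The tests in this part were chosen after the results were seen. In a scan of 296 gene families that share a symbol stem, 4 were lower and 2 higher in knockout testis by camera. Of 25 Cfap genes, which encode proteins of cilia and flagella, 0 rose and 11 fell (median −0.24, adjusted p = 2.43e-05; adjusted p = 0.977 with an estimated correlation). Of 119 Ccdc genes, 2 rose and 32 fell (median −0.17, adjusted p = 0.0199), of 14 Ift genes of intraflagellar transport 0 rose and 2 fell (−0.20, adjusted p = 0.0223), and of 12 Ttll genes, which encode tubulin-modifying ligases, 0 rose and 3 fell (−0.27, adjusted p = 0.0436). Of 11 annexin genes 5 rose and 0 fell (median 0.36, adjusted p = 0.0223), and of 20 aldehyde dehydrogenase genes 6 rose and 0 fell (0.32, adjusted p = 0.0223). The adjusted p was 0.977 with an estimated correlation for each of these families.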
